A study of Mus musculus with 6 samples.

How the data were processed

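Total RNA of TUBO cells, a line grown from a mammary carcinoma of a BALB-neuT mouse, was measured on 6 Illumina BeadChip arrays, 3 with titles beginning TMA and 3 with titles beginning TDA. The titles, the design text and the growth protocol place TMA in serum-free mammosphere medium and TDA in DMEM with serum, whereas the source names of the samples place each group in the opposite medium. The groups were therefore named by title, every difference was taken as TMA minus TDA, and the medium of either group was treated as unsettled. All 6 arrays came from 1 BeadChip, with the TMA arrays in its first 3 positions and the TDA arrays in its last 3, so chip position and group cannot be told apart. The design text speaks of triplicate experiments, and no label says whether the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

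RNA was extracted with Trizol and labelled by the standard Illumina procedure, per the labels' protocols. The first deposited table holds 1 non-normalized signal intensity per probe and array, with no detection p-value and no control probes used here, and its lowest values lay far above 0, so no background had been subtracted. The second deposited table holds log2 values that the authors had normalized between arrays by a method not given in the sources used here. Its scale was read from the values: each of its columns had a rank correlation above 0.999 with the raw intensities of the same array, and its array medians were 8.16, 8.17, 8.16, 8.16, 8.16 and 8.17 for TMA1, TMA2, TMA3, TDA1, TDA2 and TDA3. The scanner software and its version are not given in the sources used here.

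Intensities were corrected with the normexp method and an offset of 50, normalized between arrays by quantiles and converted to log2 values in limma 3.58.1 under R 4.3.3. Differences are therefore on the scale of log2 of the corrected signal plus the offset, which understates the change of dim genes. Without detection p-values no probe could be called above background. Of 25697 probes, 23846 had 1 gene symbol in the platform annotation, 0 had several and 1851 were unnamed here. The Entrez identifiers of 23830 probes matched the gene table, and 0 symbols needed an update. Probes whose mean log2 value over all 6 arrays exceeded the median of all probes were tested, which left 12848 probes, 11958 of them named, for 8964 genes. A gene was represented by its probe with the highest mean.

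The groups were compared with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. The fit had 4 residual degrees of freedom and 8.14 prior degrees of freedom, and the median standard error over tested probes was 0.221. Before the data were examined, 28 gene lists were fixed, among them fibroblast, leukocyte, endothelial and adipocyte markers for other cells a culture could hold. The 24 lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over those lists, and again with an estimated correlation. The second form takes p from the 4 residual degrees of freedom, so p can rise without any correlation between genes. The rule for named genes, also fixed beforehand, took the 8 largest rises and the 8 largest falls among genes past the threshold whose groups did not overlap. From each tested list it took up to 3 members past the threshold with the largest differences, or the 2 with the smallest p where none passed. Erbb2, which the rule would also name, was not analysed here. Dhx58, the genes of the other-cell lists and the genes of 9 lists added after the largest differences had been seen were named outside this rule, after their values were seen. The added lists were adjusted over those 9 lists alone. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

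The procedure was tested on simulated data for the same comparison over 12848 probes, with errors drawn independently for each probe. It recovered 24 of 50 probes changed by 1 on the log2 scale, 37 of 50 changed by 1.5, 48 of 50 changed by 2 and 50 of 50 changed by 3, with 8 false calls. It called 0 probes where nothing had been changed, and it recovered 1 of 1 shifted list and called 0 of 20 unshifted lists. These lists held probes with independent errors, so they cannot show how often lists of genes that move together are called wrongly. The estimated correlations of the real lists ranged from -0.0696 for metallothioneins and zinc transport to 0.826 for mitosis. The number of arrays limits the precision of every value.

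The alternatives tried were no background correction, an offset of 16, median scaling, cyclic loess, the authors' log2 table, no filter, a stricter filter keeping probes above the 75th percentile of mean log2 values, each array left out in turn, the replicate number as a block, eBayes with a trend and robust prior, array quality weights, an unmoderated test, 1 probe per gene and, for lists, the mean over the probes of a gene. The fit without TMA1 and TDA1 together and the counts of list members without each array were added after the data had been seen.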

Results

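Transcript levels of adherent TUBO cells, a mouse mammary carcinoma line, were measured on 6 single-colour bead arrays to ask which expression profile goes with mammosphere medium as opposed to standard medium. By title, the 3 TMA arrays carry RNA of cells in serum-free DMEM-F12 containing bFGF and EGF, both growth factors at 20 ng/ml, with insulin at 5 μg/ml and albumin at 0.4%, and the 3 TDA arrays RNA of cells in DMEM with 20% fetal calf serum. The source names of the same samples state the reverse. Each value below therefore compares the arrays titled TMA with those titled TDA, and the medium behind a direction is unsettled. The mean raw signal per probe was 626, 615 and 635 for TMA1, TMA2 and TMA3 and 845, 582 and 560 for TDA1, TDA2 and TDA3, over 25697 probes each.

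The first principal component held 45.6% of the variance over tested probes and parted the groups, with TMA1 at -5.74, TMA2 at -37.3 and TMA3 at -29.4 against 23.2, 28.9 and 20.4 for TDA1, TDA2 and TDA3. TMA1 thus lay nearest the TDA arrays. The second component held 25% and set TDA2 at -36.3 apart from TDA3 at 26.6. Across probes, which are not independent replicates, the log2 values of TMA1 correlated with those of TDA1 at r = 0.955, against 0.947 with TMA2 and 0.955 with TMA3, and those of TDA2 and TDA3 correlated at r = 0.935.

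**Figure D1:**
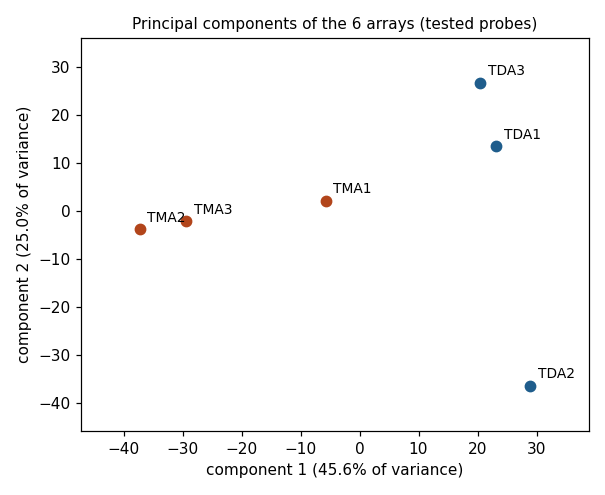
First and second principal components of the log2 values of the 12848 tested probes, 1 point per array, coloured by the group in the title, with the share of variance on each axis. The TMA arrays lie at or below -5.74 on the first axis and the TDA arrays at or above 20.4.

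The strongest rise on the TMA arrays was that of Ccl5, a chemokine that attracts T cells and monocytes, at 12.06 ± 1.20 against 7.53 ± 0.33 (log2, mean ± SD, n = 3 each), a log2 difference of 4.53 with a standard error of 0.45 (limma adjusted p = 0.00341). Txnip, the thioredoxin-interacting protein that limits glucose uptake, rose by 3.30 (adjusted p = 0.00828), and its arrestin-domain relative Arrdc4 rose by 2.08 (adjusted p = 0.00724). The secreted matrix protein Ecm1 rose by 2.83 ± 0.30 (standard error, adjusted p = 0.00341). The matricellular proteins Ccn2 and Ccn1 rose by 2.51 and 1.85, and the serine proteases Prss22 and Prss27 by 2.10 and 2.07, with adjusted p between 0.00988 and 0.0426. Other tested probes read 0.83 and 1.68 for Ccn1, neither past the threshold, and 1.84 and 0.71 for Prss27, the first past it. Of the 8 largest falls, 7 belonged to replication-dependent H2A histone genes, which package newly made DNA: H2ac22, H2ac15, H2ac24, H2ac10, H2ac12, H2ac7 and H2ac11 had log2 differences of -3.02, -2.99, -2.97, -2.94, -2.87, -2.85 and -2.80, with adjusted p between 0.00828 and 0.0130. The coding sequences of this family are nearly identical, so a probe for 1 of these genes may read others. Klk10, a secreted kallikrein-related protease, fell by 2.63 on the log2 scale (adjusted p = 0.00988). Of the 34 genes named by the fixed rule that passed the threshold, 7 passed without TMA2, 3 without TMA3, 3 without TDA1 and 19 without TDA3, and 18 without background correction and 11 in the authors' table.

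Of 12848 probes tested, 387 passed an adjusted p of 0.05 in limma, 196 higher and 191 lower on the TMA arrays, in 327 named genes, and 21 of these probes had no gene name here. At least a 2-fold difference was shown by 290 of them, 143 higher and 147 lower. All 387 had groups that did not overlap, as did 2955 tested probes, or 23%, where chance gives 10%. The count rested on single arrays: it was 21 without TMA2, 3 without TMA3, 8 without TDA1 and 112 without TDA3, and 682 without TMA1 and 658 without TDA2. It was 198 without background correction, 129 with median scaling, 135 in the authors' table and 232 with the stricter filter. An unmoderated test called 0 probes, and array quality weights gave 1906. The share of calls higher on TMA arrays, 50.6%, was 40.7% in the authors' table and 57.1%, 66.7%, 87.5% and 58.0% without TMA2, TMA3, TDA1 and TDA3.

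**Figure D2:**
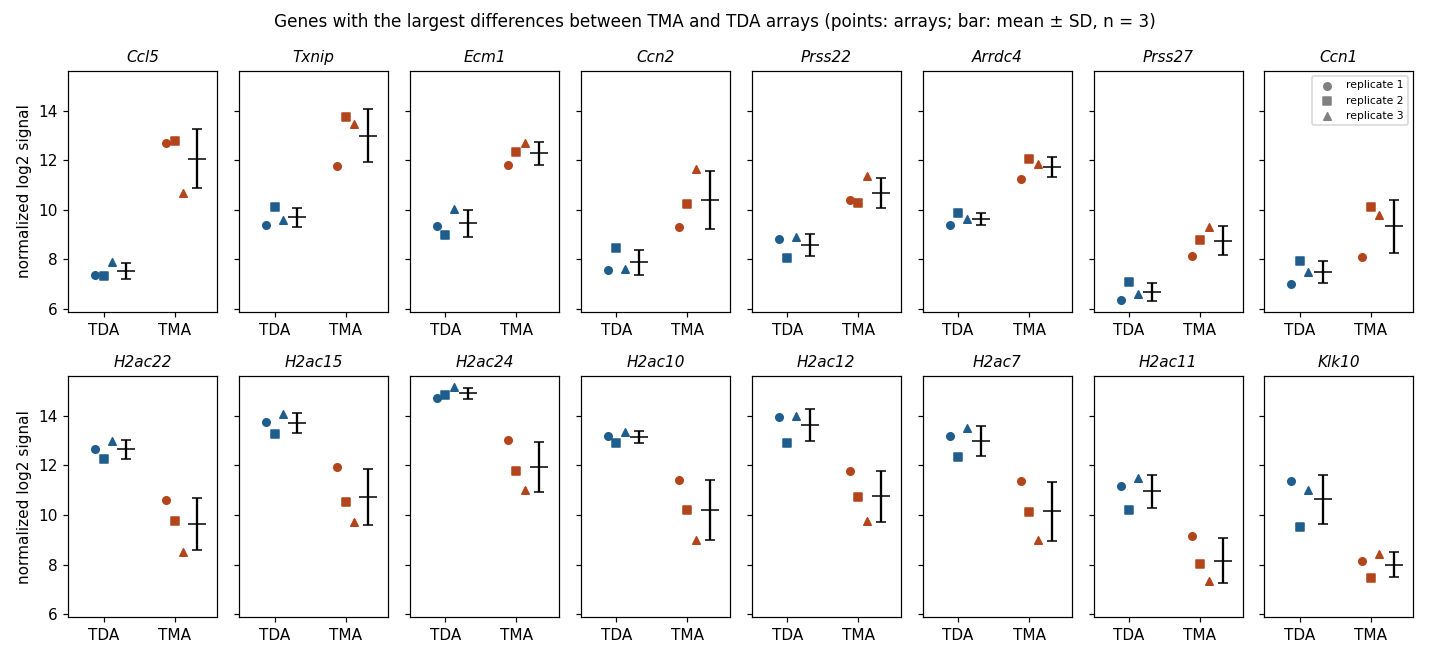
Normalized log2 values of the 8 genes with the largest rise and the 8 with the largest fall on the TMA arrays, 1 point per array, shaped by replicate number, with a bar for the mean ± SD (n = 3). For each gene the 3 TMA arrays do not overlap the 3 TDA arrays, with Ccl5 differing by 4.53 and H2ac22 by -3.02.

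Genes of cell division were lower together on the TMA arrays. Of 14 tested DNA replication genes, 11 fell and 0 rose over all probes, and 14 fell when adjusted over the list alone, with a median log2 difference of -1.21. The genes of the replicative helicase subunit Mcm5, the ribonucleotide reductase subunit Rrm2 and the thymidylate synthase Tyms had log2 differences of -2.40, -1.94 and -1.76, with adjusted p of 0.00988, 0.0200 and 0.0236, while other Tyms probes read -1.28, past the threshold, and -0.12, not past it. Of 12 mitosis genes, 8 fell and 0 rose over all probes and 12 fell adjusted over the list alone, with a median of -1.37. The survivin gene Birc5, the spindle protein gene Nusap1 and the mitotic kinase gene Cdk1 had log2 differences of -2.02, -1.85 and -1.79, with adjusted p of 0.0149, 0.0399 and 0.0234. Camera called both lists lower, with adjusted p = 8.79e-15 for replication and 6.33e-11 for mitosis, but with adjusted p = 0.254 and 0.287 with an estimated correlation. The replication list averaged 8.68, 7.89 and 8.12 on TMA1, TMA2 and TMA3 and 9.80, 9.42 and 9.58 on TDA1, TDA2 and TDA3. The mitosis list averaged 8.82, 8.24 and 8.00 on the TMA arrays in that order and 10.02, 9.04 and 10.09 on the TDA arrays, with TDA2 nearer to TMA1 than to TDA1 or TDA3. Without TMA2, TMA3 or TDA1, limma called 0 genes of either list over all probes, with 14 replication genes and 10 mitosis genes at unadjusted p under 0.05 in each case, and without TDA3 it called 2 and 0, with 14 and 10.

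Genes of amino acid supply and ribosome production were also lower as lists. Of 19 tested targets of the amino acid response factor ATF4, 1 fell over all probes, 11 fell adjusted over the list alone and 0 rose, with a median of -0.74. That gene, the serine synthesis enzyme Psat1, fell by 1.68 on the log2 scale (adjusted p = 0.0270). Of 12 ribosome biogenesis genes, 0 passed over all probes in limma, 7 had an unadjusted p under 0.05, all lower, and 4 fell adjusted over the list alone, with a median of -0.71. Its nucleolar members Nop58 and Pes1 differed by -1.09 and -1.19, with adjusted p of 0.0705 and 0.0975. Camera gave adjusted p = 2.23e-05 for the ATF4 list and 0.00314 for ribosome biogenesis, and adjusted p = 0.396 and 0.563 with an estimated correlation. Psat1 lost its call without TMA2, TMA3, TDA1 or TDA3, and without TDA2 the medians of the ATF4 and ribosome biogenesis lists were -0.44 and -0.36, with the latter's call lost (adjusted p = 0.0751). The ATF4 list averaged 11.02 on TDA2, against 10.12 and 10.03 on TDA1 and TDA3 and 10, 9.46 and 9.44 on TMA1, TMA2 and TMA3. Ribosome biogenesis averaged 9.64 on TDA2, 8.98 and 8.60 on TDA1 and TDA3 and 8.78, 8.32 and 8.37 on TMA1, TMA2 and TMA3, so the groups overlapped.

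Camera called both lists of innate immune signalling higher on the TMA arrays. Of 14 tested interferon-stimulated genes, 4 rose and 0 fell over all probes, and 7 rose adjusted over the list alone, with a median of 0.63. The antiviral genes Oasl2, Rsad2 and Bst2 rose by 1.70, 1.32 and 0.96, with adjusted p of 0.0270, 0.0117 and 0.0286, and the fourth, the RNA sensor Dhx58, rose by 0.93. The list averaged 8.32, 7.81 and 7.84 on TMA1, TMA2 and TMA3 and 7.31, 7.34 and 7.33 on TDA1, TDA2 and TDA3. Of 13 NF-kB and acute phase genes, Ccl5 and the NF-kB inhibitor gene Nfkbia rose, the latter by 1.19 (adjusted p = 0.0330), 0 fell, and 6 rose adjusted over the list alone, with a median of 0.61 and averages of 9.99, 9.60 and 9.85 on the TMA arrays and 8.88, 9.48 and 8.79 on the TDA arrays. Camera gave adjusted p = 2.70e-06 and 0.000451 for these lists, and adjusted p = 0.254 and 0.302 with an estimated correlation. Without TMA2, TMA3 or TDA1, limma called 0 interferon-stimulated genes over all probes, with 10, 8 and 8 at unadjusted p under 0.05, and without TDA3 it called 1. Nfkbia lost its call without TMA2, TMA3 or TDA1. The interferon list had a camera adjusted p of 0.0775 with the stricter filter, which left only 3 of its 14 genes to test.

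Camera also called the YAP and TEAD, FOXO and ERK lists higher. Of 5 tested targets of the transcription factors YAP and TEAD, Ccn2 and Ccn1 rose, 0 fell and 4 rose adjusted over the list alone, with a median of 0.90. Of 10 FOXO targets, Txnip and the insulin receptor substrate gene Irs2 rose, the latter by 1.42 (adjusted p = 0.0236), 0 fell and 6 rose adjusted over the list alone, with a median of 0.76. Of 14 ERK feedback and immediate early genes, the transcription factor genes Fos and Egr1 rose, by 1.71 and 1.46 (adjusted p of 0.0235 and 0.0379), 0 fell and 2 rose adjusted over the list alone, with a median of 0.31. Camera gave adjusted p = 0.000451, 0.000454 and 0.0107 for these lists, and adjusted p = 0.254 for each with an estimated correlation. Without TMA2, TMA3, TDA1 or TDA3, limma called neither Ccn2 nor Ccn1, nor Irs2, Fos or Egr1, and without TDA2 the median of the ERK list was 0.19. Txnip lost its call in limma without TMA3 or TDA1, with adjusted p up to 0.0578.

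Camera called 3 further lists higher on the TMA arrays. Of 11 p53 targets, 0 passed over all probes in limma, 5 had an unadjusted p under 0.05 and 1 rose adjusted over the list alone, with a median of 0.53. Phlda3 and Trp53inp1 differed by 0.96 and 0.92, with adjusted p of 0.0751 and 0.144. Of 10 targets of the serum response factor SRF and the actin cytoskeleton, 0 passed over all probes in limma, 4 had an unadjusted p under 0.05 and 1 rose adjusted over the list alone, with a median of 0.47. Tropomyosin gene Tpm1 differed by 0.87 and Srf itself by 0.52, with adjusted p of 0.0680 and 0.170. Of 14 epithelial junction and keratin genes, the protease inhibitor gene Spint1 rose by 1.13 (adjusted p = 0.0436), 0 fell and 3 rose adjusted over the list alone, with a median of 0.21. Camera gave adjusted p = 0.00850 for p53, 0.0332 for SRF and 0.0332 for the epithelial list, and adjusted p = 0.407, 0.312 and 0.254 with an estimated correlation. The p53 list averaged 9.49, 9.87 and 9.23 on TMA1, TMA2 and TMA3 and 8.96, 9.32 and 8.85 on TDA1, TDA2 and TDA3, so the groups overlapped, and without TMA2 its median was 0.28 and its call was lost (adjusted p = 0.0734). The SRF and epithelial calls were lost in 9 and 7 of 19 alternatives, among them SRF without TMA3, TDA2 and TDA3, with medians of 0.34, 0.29 and 0.31, and the epithelial list without TMA3 and TDA2, while its median was 0.31 without TMA1, and Spint1 lost its call without TMA2, TMA3, TDA1 or TDA3.

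**Figure D3:**
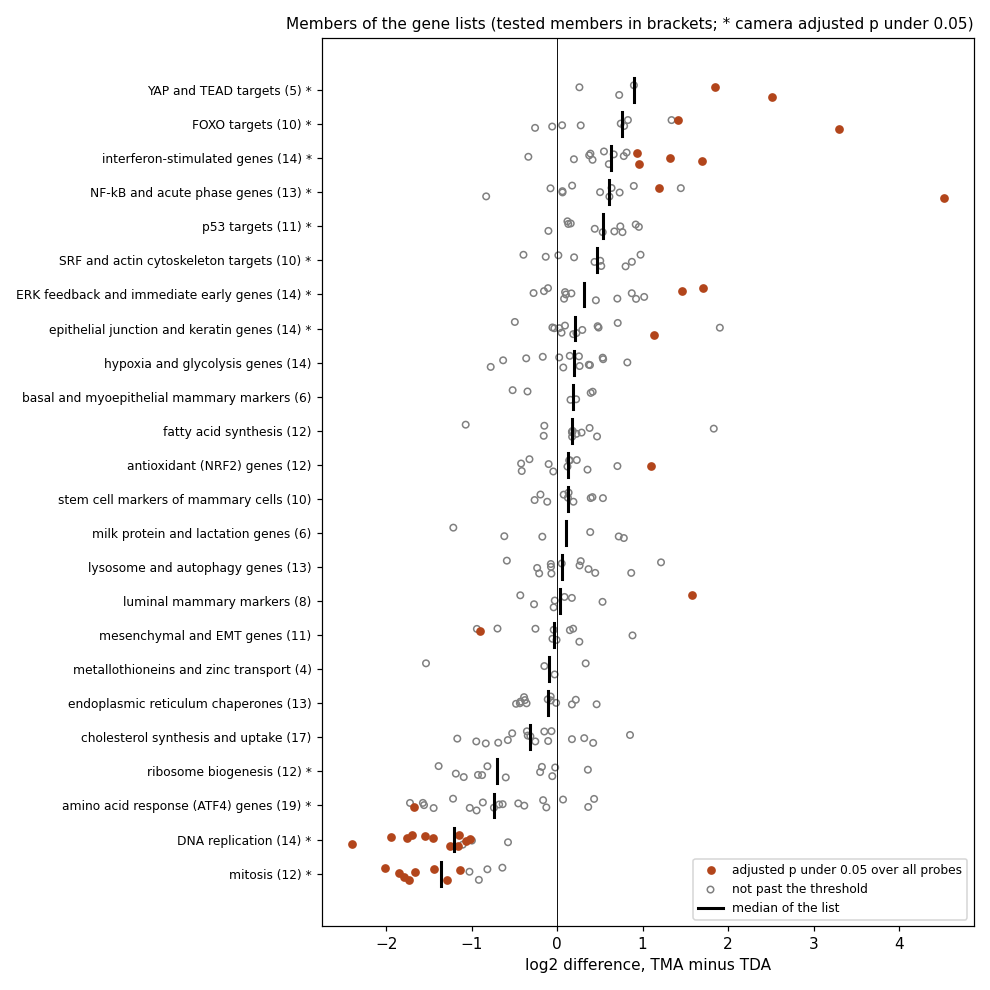
Log2 difference, TMA minus TDA, of the tested members of each gene list, 1 point per gene, filled where the adjusted p over all probes was under 0.05, with a vertical bar at the median of the list, the number of tested members in brackets and an asterisk where camera's adjusted p was under 0.05. The DNA replication list has its median at -1.21 and the YAP and TEAD list at 0.90.

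Mammary lineage and stem cell markers were not called as lists by camera at either correlation. The filter left part of each list untested. Of 20 stem cell, 12 luminal, 14 basal, 17 mesenchymal and 11 milk genes on the array, 10, 8, 6, 11 and 6 were tested. Of 10 stem cell markers, 0 passed over all probes or adjusted over the list alone in limma, 0 had an unadjusted p under 0.05, and the median was 0.13, with Aldh1a3 at 0.54 and Itga6 at 0.39 (camera adjusted p = 0.489). Of 8 luminal markers the mucin gene Muc1 rose by 1.57 (adjusted p = 0.0403), the only 1 to pass over all probes or adjusted over the list alone, though its 3 other probes, at 0.95, 1.15 and 0.89, did not pass, with a list median of 0.03 (camera adjusted p = 0.489). Of 6 basal markers, 0 passed over all probes or adjusted over the list alone and 0 had an unadjusted p under 0.05, with Col17a1 at -0.35 and Lamb3 at 0.42 and a median of 0.19 (camera adjusted p = 0.692). Of 11 mesenchymal genes the growth factor gene Tgfb1 fell by 0.90 on the log2 scale (adjusted p = 0.0450), 0 rose, and 1 rose and 3 fell adjusted over the list alone, with a median of -0.04 (camera adjusted p = 0.489). Of 6 milk protein and lactation genes, 0 passed over all probes, 4 had an unadjusted p under 0.05 and 2 rose and 1 fell adjusted over the list alone, with Plin2 at 0.78 and Xdh at 0.72. Its median was 0.11 and its mean -0.02, of opposite sign (camera adjusted p = 0.759). With 1 array left out, medians ranged from 0.04 to 0.27 for stem cell markers, 0.00 to 0.14 for luminal markers and -0.18 to 0.09 for mesenchymal genes. Muc1 lost its call without TMA1, TMA2, TMA3 or TDA1, and Tgfb1 without TMA2, TMA3, TDA1, TDA2 or TDA3.

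Lipid, stress and metabolic lists were not called by camera. Of 17 cholesterol synthesis and uptake genes, 0 passed over all probes or adjusted over the list alone in limma and 3 had an unadjusted p under 0.05, with the sterol enzymes Sc5d at 0.85 and Lss at -1.17, a median of -0.31 and camera adjusted p = 0.140. That list was called lower without TMA1 (adjusted p = 0.0211), without TDA2 (adjusted p = 0.000345) and with array quality weights (adjusted p = 0.00275). Of 12 fatty acid synthesis genes, 0 passed over all probes, 2 had an unadjusted p under 0.05 and 1 rose and 1 fell adjusted over the list alone, with the desaturase gene Scd1 at 1.83, the elongase gene Elovl6 at -1.07 and a median of 0.18 (camera adjusted p = 0.338). Of 12 antioxidant genes, Gstm1, a glutathione transferase, rose by 1.10 (adjusted p = 0.0263), and it was the only 1 to rise adjusted over the list alone (camera adjusted p = 0.489). Of 4 metallothionein and zinc transport genes, 0 passed over all probes and 1 had an unadjusted p under 0.05 and fell adjusted over the list alone, with Mt1 at -1.54 and Slc39a10 at 0.33 (camera adjusted p = 0.489). Medians were 0.20 over 14 hypoxia and glycolysis genes, with Vegfa at 0.82 and Pfkp at -0.78, -0.11 over 13 endoplasmic reticulum chaperones, with Dnajb9 at 0.46 and Pdia6 at -0.48, and 0.05 over 13 lysosome and autophagy genes, with Gabarapl1 at 1.21 and Map1lc3b at 0.87. In these 3 lists 0 genes passed over all probes in limma, with 3, 1 and 3 at unadjusted p under 0.05, while 1, 0 and 2 rose and 0 fell adjusted over the list alone, and camera adjusted p was 0.511, 0.345 and 0.489. With 1 array left out, medians ranged from -0.50 to -0.12 for the cholesterol list, 0.06 to 0.19 for antioxidant genes, -0.26 to 0.05 for metallothioneins, -0.30 to -0.16 for chaperones and -0.15 to 0.31 for lysosome and autophagy genes, the last with camera adjusted p = 0.0524 without TDA2. They also changed sign for fatty acid synthesis, from -0.0713 to 0.366, and for hypoxia and glycolysis, from -0.382 to 0.435. Gstm1 lost its call without TMA2, TMA3 or TDA1.

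Markers of other cell types were mostly too dim to be tested. Of 10 fibroblast, 10 leukocyte, 8 endothelial and 6 adipocyte markers on the array, 2, 2, 2 and 1 passed the filter, too few for camera. Limma called 0 of these 7 over all probes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. The collagen genes Col1a2 and Col6a2 differed by -0.10 and 0.05, the leukocyte genes Csf1r and Cd14 by -0.31 and -0.60, the endothelial genes Pecam1 and Kdr by 0.36 and -0.19, and the adipocyte gene Lep by -0.23. Csf1r and Cd14 together averaged 10.79, 10.4 and 10.45 on TMA1, TMA2 and TMA3 and 10.99, 10.93 and 11.09 on TDA1, TDA2 and TDA3. The average signal of these 2 leukocyte genes was therefore not low, though it does not give the level of each gene. Their averages did not overlap between the groups, as was also so for 23% of all tested probes.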

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

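The mean raw signal per probe of TDA1, 845.4, stood apart from the other 5 arrays, which lay between 560.2 and 634.9: its gap to the nearest array was 0.738 of the whole range. Chance sets a sample apart in this way in about 1 of 20 groups. The medians of the raw signals were closer, 309.6 on TDA1 against 270.6 to 287 on the others. Quantile normalization gives every array the same distribution, and TDA1 then received the highest quality weight of the 6 arrays, 3.08.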

How the results depend on the processing

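The fit without TMA1 and TDA1 together, which called 153 probes, was chosen after the data had been seen. Against 387 probes, the count was 198 without background correction, 129 with median scaling, 135 in the authors' table, 232 with the stricter filter and 1906 with array quality weights, and 3 to 682 when 1 array was left out. An unmoderated test called 0, with 1793 probes at unadjusted p under 0.05 against 2379 in limma, and a lowest adjusted p of 0.239. Of the 34 named genes past the threshold, 18 passed without background correction, 11 in the authors' table and 3 to 33 when 1 array was left out. No named gene past the threshold changed sign in the 17 alternatives tabulated gene by gene, which leave out the fit on 1 probe per gene and the unmoderated test: 398 of 573 values stayed past it and 175 did not. Ccl5 and Ecm1 passed in all of those 17, with adjusted p up to 0.0466, but not in the unmoderated test. The 12 lists called by camera became 0 with an estimated correlation, and 10 to 13 when 1 array was left out. For the ERK and epithelial lists the estimates, -0.0435 and -0.0479, lay below the preset of 0.01. Camera's unadjusted p still rose, from 0.00445 to 0.0390 for ERK and from 0.0166 to 0.0635 for the epithelial list. With an estimated correlation camera also takes p from the 4 residual degrees of freedom of the fit, not from the number of genes. The lost calls therefore do not measure correlation between genes alone, and part of the loss comes from this change. Medians of called lists moved by more than 1.5 times, with the direction kept, to 0.35 for YAP and TEAD, 0.28 for FOXO, 0.13 for ERK, 0.14 for SRF, 0.18 for NF-kB and -0.29 for ribosome biogenesis without a filter, which adds dimmer genes. In the authors' table they were 0.51 for YAP and TEAD, 0.18 for ERK, 0.24 for SRF, 0.07 for epithelial genes, 0.33 for interferon, 0.33 for NF-kB, 0.35 for MHC class I and 0.15 for the proteases, and without background correction 0.51 for YAP and TEAD, 0.24 for SRF, 0.34 for interferon and 0.14 for the proteases. They were 0.70 for ERK, 0.39 for interferon, -0.54 for nucleotide synthesis and 0.52 for the proteases with the stricter filter, 0.09 for epithelial genes with median scaling, and -0.54, 0.50 and -0.31 for nucleotide synthesis, the proteases and histones other than H2A without TMA1 and TDA1. Camera's direction turned, never with a call, at these medians: milk genes -0.00898 with median scaling, -0.128 without a filter and -0.0173 without TMA3, basal markers -0.0347 without a filter and 0.0938 without TDA3, fatty acid synthesis -0.00830 without TMA1 and -0.157 with array weights, and hypoxia and glycolysis -0.382 without TDA2 and -0.271 with array weights. The added ribosomal protein list turned at medians of 0.0105 without background correction, 0.0127 without a filter, 0.102 without TMA3, 0.0508 without TDA2 and 0.00485 with array weights. With 1 array left out, these medians ranged from -0.0713 to 0.366 for fatty acid synthesis, 0.0938 to 0.299 for basal markers, -0.157 to 0.347 for milk genes, -0.382 to 0.435 for hypoxia and glycolysis and -0.0945 to 0.102 for ribosomal proteins. With fewer arrays the fit has fewer degrees of freedom, and otherwise the cause was not tested. With the replicate number as a block, 518 probes, 12 lists and 33 named genes passed. Deviations of arrays with the same number correlated at 0.126, 0.0133 and 0.0269 for numbers 1, 2 and 3, and TMA2 correlated better with TDA3 than with TDA2. The deviations sum to 0 within each group, which ties these correlations to each other. They therefore neither show nor exclude that arrays with the same number were paired. Without detection p-values, how far dim probes lay above background is unknown.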

Other observations

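The 9 gene lists below were chosen after the largest differences had been seen, as were both tests of histones and those of the position and mixing of TMA1; the tests of the media and of the splits were planned. Camera called proteasome subunit genes lower on the TMA arrays: all 22 tested members had a negative difference, with a median of -0.38, 1 fell over all probes and 6 fell adjusted over the list alone. It gave adjusted p = 2.63e-06, and adjusted p = 0.0480 with an estimated correlation, the only list of the 9 below the threshold at both, and it stayed called in all 19 alternatives. The regulatory particle subunit gene Psmd14 fell by 0.94 on the log2 scale (adjusted p = 0.0416). Of 19 nucleotide synthesis genes, 4 fell over all probes and 5 adjusted over the list alone, among them the nucleoside diphosphate kinase gene Nme1, which fell by 1.98, and the folate enzyme gene Mthfd1, which fell by 1.25 on the log2 scale (camera adjusted p = 5.90e-05, and adjusted p = 0.0572 with an estimated correlation). Of 37 respiratory chain genes, the cytochrome oxidase gene Cox5b alone fell over all probes, by 1.04 on the log2 scale, and 0 adjusted over the list alone, with 2 at unadjusted p under 0.05 in limma (camera adjusted p = 0.00257, adjusted p = 0.0706 without TDA3, and adjusted p = 0.134 with an estimated correlation). Without TMA2, TMA3 or TDA1, limma called 0 genes of these 3 lists over all probes, and at unadjusted p under 0.05 were 7, 6 and 8 proteasome, 5, 7 and 7 nucleotide synthesis and 3, 2 and 1 respiratory chain genes. Without TDA3 it called 0 proteasome genes, with 10 at unadjusted p under 0.05, 1 nucleotide synthesis gene and 0 respiratory chain genes, with 4. Without TDA2 it called 0 respiratory chain genes, with 5.

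Of 15 genes of antigen presentation by MHC class I, 2 rose over all probes and 7 adjusted over the list alone: the light chain gene B2m rose by 1.07 (adjusted p = 0.0178) and H2-Q7 by 0.97 (adjusted p = 0.0262). Camera gave adjusted p = 2.43e-05, and adjusted p = 0.134 with an estimated correlation, and without TMA2, TMA3 or TDA1 limma called 0 of its genes, with 9, 5 and 6 at unadjusted p under 0.05. Among 13 trypsin-like and kallikrein proteases and their inhibitors, Prss22, Prss27 and Tmprss2 rose over all probes, the last by 1.34, and Klk10 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.00996, adjusted p = 0.186 with the stricter filter, and adjusted p = 0.134 with an estimated correlation), and the median of 0.28 was 0.47 without TMA2. Without TMA2, 1 of these 4 genes passed, and 0 without TMA3 or TDA1, with 5 genes at unadjusted p under 0.05 in each case. The stricter filter left 7 of the 13 genes to test. Of 28 ribosomal protein genes, 0 passed over all probes, 5 had an unadjusted p under 0.05 in limma and 1 rose and 1 fell adjusted over the list alone, with a median of 0.01, a mean of -0.02 and camera adjusted p = 0.923. Of 17 cytosolic chaperone genes, 0 passed over all probes, 5 had an unadjusted p under 0.05 and 1 rose and 1 fell adjusted over the list alone, with a median of -0.26 and camera adjusted p = 0.105, called only in the authors' table (adjusted p = 0.0429).

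The titles and the source names give the groups opposite media, and as a check fixed beforehand cells without serum lipoproteins would raise cholesterol synthesis genes, a list with a median difference of -0.3141, which camera did not call (adjusted p = 0.140, and adjusted p = 0.702 with an estimated correlation). It was called lower, the direction that exchanged titles would give, without TMA1 (median -0.50, adjusted p = 0.0211), without TDA2 (-0.49, adjusted p = 0.000345) and with array quality weights (-0.53, adjusted p = 0.00275), but without TMA3 its median was -0.12 and without TDA3 its adjusted p was 0.717, so it does not settle the matter. Serum would raise SRF targets, and that list had a median of 0.4701 and was called higher on the TMA arrays (adjusted p = 0.0332), which is what exchanged titles would give. That evidence is weak: adjusted p = 0.312 with an estimated correlation, 0 members passed over all probes with 4 at unadjusted p under 0.05 in limma, and the call was lost in 9 of 19 alternatives. Nor could this list tell an effect of serum from one of the bFGF and EGF that the TMA medium holds by title. The cholesterol and SRF lists were the only checks fixed for the media, and no other list was weighed for or against either medium. Which medium the TMA cells had remains open, and with it every statement that ties a direction to a medium.

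The median log2 difference lay lower for H2A histone genes than for other histone genes, a gap that was not itself tested, and 2 explanations were weighed. Of 13 tested H2A genes, 9 fell over all probes and adjusted over the list alone, with a median of -2.80 (camera adjusted p = 1.22e-08, and adjusted p = 0.134 with an estimated correlation), and 3, 1, 0 and 7 fell without TMA2, TMA3, TDA1 and TDA3, with 9 at unadjusted p under 0.05 without TDA1. If 1 H2A transcript were read by all of these probes, the H1, H2B, H3 and H4 genes might lie near 0, but the median of those 29 genes was -0.6046, with a 95% bootstrap interval over genes of -0.751 to -0.339, which excludes 0, treats genes that moved together as independent and includes the bound of -0.5, which was set after the H2A falls but before these values had been seen. Of them 0 passed over all probes (10 fell and 2 rose without TDA2), with 11 at unadjusted p under 0.05 in limma, and 2 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.000340, adjusted p = 0.0604 without TMA1 and TDA1, and adjusted p = 0.376 with an estimated correlation), and their median was -1.09 without TDA2, -0.37 without TMA3 and -0.30 without TDA3, with averages of 8.53 on TMA2 and 7.96 on TDA2, so that the groups overlapped, and cross-reading within the family remains open. A fall in replicating cells is another candidate explanation: as deviations from the group means, the H2A and DNA replication averages of the 6 arrays correlated at 0.6328, below the 0.8 asked for and above 0, over too few arrays to decide.

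TMA1 lay nearer the TDA arrays than TMA2 and TMA3 did: over the 200 probes with the smallest p without it, used because too few passed without TMA3 or TDA1 to use the called probes first intended, TMA1 stood at a median position of 0.5128 between the TDA mean at 0 and the mean of the other TMA arrays at 1, with quartiles of 0.375 and 0.643, against 1.05 for TMA2 and 1.03 for TMA3. TDA2, measured likewise from the TMA mean, stood at 0.637, with quartiles of 0.357 and 0.885, against 0.888 for TDA1 and 0.854 for TDA3, a smaller displacement with wider quartiles, so single arrays varied along this axis in both groups and array noise remains open. Partial mixing with TDA RNA would need 1 share for all probes, but the median share of TDA signal that TMA1 needed was 0.647 for probes higher and 0.286 for probes lower on the TMA arrays, a difference of 0.3611. That difference was 0.466 on TDA2, with shares of 0.139 and 0.604, so mixing is not excluded either. The positions are also tied to each other, since the reference at 1 included TMA1 for TMA2 and TMA3, and TDA2 for TDA1 and TDA3. An array nearer the other group thus raises the positions of the others in its own group. The bounds first written against noise and against mixing were both met. Both verdicts were made more cautious after the values of all arrays had been compared. TMA1 was not nearer the TDA arrays throughout: the interferon list averaged 8.32 on TMA1 against 7.81 and 7.84 on TMA2 and TMA3, and the NF-kB list 9.99 against 9.60 and 9.85, and no biological explanation was tested.

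Of the 10 ways to split the 6 arrays into 3 and 3, 1 gave as many called probes as the real split, the real split itself with 387. The highest other count was 4, and 10 splits are too few for a share under 0.05.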
